A study of Mus musculus with 13 samples.

How the data were processed

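Messenger RNA was measured by bulk RNA sequencing in 13 libraries from 7 male wild-type C57BL/6 mice aged 12 to 16 weeks. Some mice received a controlled cortical impact (CCI), a model of traumatic brain injury in which a driven piston strikes the exposed cortex, and others a sham operation. The hemisphere on the side of surgery (ipsilateral) and the opposite one (contralateral) were collected 4 days later as separate samples. Per the labels' protocols, the mice were perfused, the tissue was kept in an RNA-preserving solution, RNA was extracted with TRIzol, and libraries were made from polyadenylated RNA with a stranded kit.

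The labels give 4 groups: CCI ipsilateral (n = 4, animals 1, 2, 3 and 5), CCI contralateral (n = 4, the same animals), sham ipsilateral (n = 2, animals 4 and 6) and sham contralateral (n = 3, animals 4, 6 and 8). The number in a sample's name is the animal's, so equal numbers pair the hemispheres of an animal. The names mark every ipsilateral library RH and every contralateral one LH, read here as right and left hemisphere. Their leading numbers also fall in separate ranges. Within CCI or sham mice the side of surgery therefore cannot be told apart from right or left. Deviations from the group means correlated between the hemispheres of an animal at 0.0035 to 0.088 and between different animals at -0.06 to 0.027. As planned, the animal was entered as a block in an alternative for the comparisons within animals, and not in the main design. The limma voom fit with the animal as a random effect estimated a correlation of 0.16 between the libraries of an animal. CCI and sham animals share no number, so the comparisons of CCI with sham have no paired form.

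The authors deposited expected counts per gene estimated by RSEM, per the file headers and the submitters' processing notes, and these counts are not normalized. The authors also deposited TPM, an abundance scaled for gene length and library size, per the file headers. A further deposited table holds the authors' own DESeq2 comparisons, with a log2 estimate per gene. In it the authors give a signed fold change as a score, per the file header. The same table holds the authors' raw p-value and Benjamini-Hochberg p-value. The submitters' processing notes name bcl2fastq, RSEM, DESeq2 and the GRCm38 (mm10) genome, without versions. The aligner and its settings are not given in the sources used here. Whether the counting used the strand is not given in the sources used here either, so genes overlapped on the opposite strand can share reads. Copies with near-identical sequence are divided by RSEM's model and are less certain.

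The count table has 43411 genes. Of its values 9.76% were not whole, and all were rounded to whole numbers for the count tests. Totals ran from 5604856 to 7955076 counts per library. Between replicates of a group, chi-square per degree of freedom over genes was 2.06 to 3.99 for every pair, above sampling noise, so no library was treated as a duplicate. Gene positions came from GENCODE M21 on GRCm38, matched by identifier for 99.5% of genes; each position is that of the whole gene, and the counts cover its exons.

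The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, robust, R 4.3.3) with TMM scaling and edgeR's group-wise filter on low counts, which left 14875 genes. One model with 4 group means was fitted to the 13 libraries, which share 1 estimate of the spread because sham ipsilateral has 2 libraries. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The 5 comparisons were CCI with sham in each hemisphere, ipsilateral with contralateral in CCI and in sham, and the difference between these hemisphere effects. Each adjusted p below is edgeR's unless another method is named. CPM, counts scaled to library size by TMM, are given as mean ± SD. Folds are 2 to the power of the fitted log2 fold change. Each SE was derived as the absolute log2 fold change over the square root of edgeR's F statistic, and is approximate. Where a group had 0 counts of a gene, the fold is a lower bound against 3 counts over that group. Where it had 1 to 3, the ratio of summed counts is given with an exact 95% interval. Intervals and floors cover counting error only.

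Lists of genes were tested with camera (limma 3.58.1) on voom log2 CPM with a preset correlation of 0.01 between genes, again with the correlation estimated from the data, and with fry. Adjustment was over the 44 lists within a comparison. The lists cover cell types that the tissue holds or that can enter it, brain regions a dissection can differ in, inflammatory and interferon genes, injury responses, and signs of RNA quality. They hold 618 genes, of which 614 had a row in the count table; the others were not analysed here. The groups, main tests, alternatives, gene lists and rule for named genes were chosen before the data were examined.

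Genes were named by 3 rules. The first took the 8 largest positive and 6 largest negative log2 fold changes (5 and 5 in the contralateral, sham and difference comparisons) among genes past the threshold with an average log2 CPM of at least 2, groups that did not overlap and an established symbol. The second took up to 4 members with the smallest p from each list described. The third took 26 fixed genes of inflammation, microglia, astrocytes and interferon response whatever their outcome. Of these, 22 passed the filter; the other 4 are given as counts. Where the fixed genes are many, counts and ranges stand for the rest. Some genes that these rules name are not reported here.

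The test was also run on simulated counts for the 14875 genes, with 67 of them changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. At 2-fold, it recovered 74.6% in CCI ipsilateral against sham ipsilateral, 88.1% in CCI contralateral against sham contralateral, 79.1% in CCI ipsilateral against contralateral, 79.1% in sham ipsilateral against contralateral and 61.2% for the difference of effects. At 1.5-fold these shares were 62.7%, 62.7%, 67.2%, 50.7% and 49.3%, in the same order. Of all calls in the simulation, 3 of 157, 11 of 173, 11 of 175, 8 of 160 and 7 of 139 were false, again in that order. Simulated counts were drawn independently for each gene and library, with no effect of animal or dissection. Calls in the real data were far fewer contralaterally and between sham hemispheres, so the shares recovered can be too high there.

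The alternatives were DESeq2 1.42.0, limma voom with the animal as a random effect, median-of-ratios and upper-quartile scaling, no filter on low counts, a filter of 1 CPM in at least 4 libraries, a fit of only the groups compared, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), the animal as a replicate block, and the omission of each library in turn. The 1 CPM filter had been planned as stricter but kept 15143 genes, more than the main filter. Added after the data were seen were a block fit of the 6 animals with both hemispheres and a fit without the CCI contralateral libraries of animals 1 and 5, whose hypothalamic or pituitary genes stood apart. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for annotation and figures.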

Results

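Gene expression was measured in 13 brain hemispheres of 7 mice, 4 days after controlled cortical impact (CCI) or a sham operation. The series title concerns macrophages that depend on Ccr2, the receptor that draws monocytes into tissue, and the type I interferon response of microglia, the resident immune cells of the brain. These libraries are of whole hemispheres, so a change in a gene can come from its level per cell or from the number of cells that express it. Total counts were 7126708 to 7955076 in the 4 CCI ipsilateral libraries and 5604856 to 7444568 in the 4 CCI contralateral ones. They were 5908022 to 6874956 in the 2 sham ipsilateral and 6578614 to 6855548 in the 3 sham contralateral libraries.

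The CCI ipsilateral libraries stood apart from the others. Over the 500 most variable genes, the first principal component held 50.9% of the variance, and the CCI ipsilateral libraries lay between 22.6 and 34.4 on it, against -18.3 to -5.1 for the other 9. The second component held 6.31%, and the sham ipsilateral libraries of animals 4 and 6 lay at -13.3 and -11.4 on it, against -5.55 to 9.76 for the other 11. Mitochondrially encoded genes took 7.6% ± 0.562 of counts (SD, n = 4) in CCI ipsilateral libraries, 8.12% ± 0.212 (n = 4) in CCI contralateral, 8.56% ± 0.658 (n = 2) in sham ipsilateral and 8.6% ± 0.346 (n = 3) in sham contralateral libraries.

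**Figure D1:**
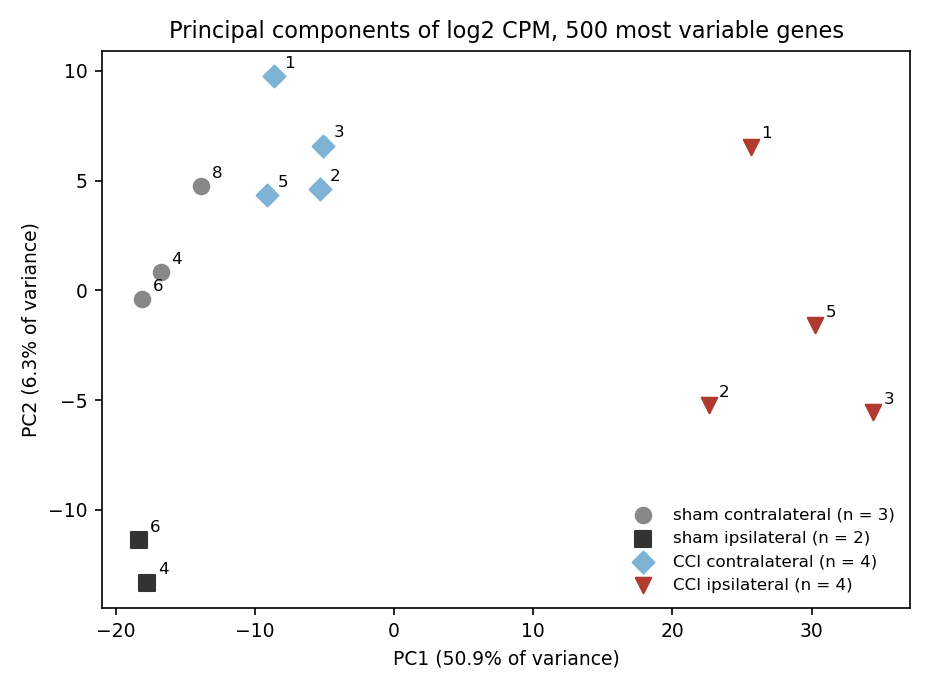
Position of each of the 13 libraries on the first (x axis, 50.9% of variance) and second (y axis, 6.31%) principal components of log2 CPM over the 500 most variable genes; symbols give the group and numbers the animal. The 4 CCI ipsilateral libraries lie between 22.6 and 34.4 on the first component and the other 9 between -18.3 and -5.1.

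CCI was first compared with sham in the ipsilateral hemisphere, which shows what differed on the side of the impact. Genes of monocytes and macrophages, activated microglia, complement, lysosomes, reactive astrocytes and cell division rose there, with list medians of 1.87 to 3.04 on the log2 scale. Immediate early genes, which neurons switch on with activity, fell with a median of -1.20. Genes of synapses, excitatory neurons and cholesterol synthesis fell by less, with medians of -0.35, -0.39 and -0.50. Cell division and cholesterol synthesis lost their calls with an estimated correlation (adjusted p = 0.129 and 0.0543). Of 14875 genes tested, 1859 rose and 1493 fell, 22.5% in all. At least 2-fold changes numbered 730 upward and 44 downward. Tested with limma on log2(TPM + 1), 1912 genes were higher and 699 lower, so that the share of higher genes was 73.2% instead of 55.5%. Without the sham ipsilateral library of animal 6, 1695 genes were called in place of 3352. The authors' deposited table calls 1704 genes higher and 1157 lower in this comparison.

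Of the 8 largest increases by the naming rule, 4 were in members of the activated microglia list (Spp1, Gpnmb, Lgals3 and Clec7a). Spp1 (ENSMUSG00000029304.12, chromosome 5, 104435118 to 104441050), encoding the secreted protein osteopontin, went from 17 ± 0.556 CPM (SD, n = 2) to 608 ± 124 CPM (n = 4). That was 35.7-fold (log2 fold change 5.16 ± 0.30 SE, edgeR adjusted p = 1.75e-06). Gpnmb (ENSMUSG00000029816.8, chromosome 6, 49036546 to 49070929), a glycoprotein of lipid-laden macrophages, rose 52.3-fold (log2 fold change 5.71 ± 0.48 SE, edgeR adjusted p = 2.23e-05). Lyz2, the lysozyme of myeloid cells, rose 47.5-fold and Lgals3, encoding galectin-3, 72.7-fold. Hmox1, the haem-degrading enzyme haem oxygenase 1, rose 27-fold from 3.75 ± 0.675 to 102.5 ± 22.8 CPM. Tgm1, encoding a transglutaminase (ENSMUSG00000022218.13, chromosome 14, 55700009 to 55713926), had 1 count in the sham ipsilateral libraries and 890 in the CCI ipsilateral ones, a ratio of 358 (95% counting interval 64.1 to 14200; edgeR adjusted p = 1.14e-05). Clec7a, the receptor dectin-1, had 3 and 301 counts, a ratio of 40.4 (13.7 to 197). C3, the central complement component, rose 22.9-fold to 11.5 ± 2.87 CPM. That fold rests on 4 and 2 counts in the sham ipsilateral libraries of animals 4 and 6. The sham contralateral libraries of animals 4, 6 and 8 had 9, 9 and 4 counts of C3.

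Of 22 activated microglia genes tested, 21 rose, and 22 when adjusted over the list alone (camera adjusted p = 1.37e-27). Cd68, a lysosomal protein of phagocytes, rose 9.27-fold (log2 fold change 3.21 ± 0.17 SE, edgeR adjusted p = 1.2e-14), and the lipid receptor gene Trem2 and the lipoprotein gene Apoe rose 4.15-fold and 1.72-fold. Of 14 homeostatic microglia genes 13 rose, also when adjusted over the list alone, with a smaller median of 0.87 (camera adjusted p = 5.55e-12; adjusted p = 0.0694 with an estimated correlation). The fractalkine receptor gene Cx3cr1 rose 2.28-fold, the integrin gene Itgam 2.98-fold and Aif1, which encodes Iba1, 4.04-fold. Tmem119 rose 1.58-fold (edgeR adjusted p = 0.00249), and without the sham ipsilateral library of animal 6 its adjusted p was 0.152. P2ry12, the purinergic receptor of resting microglia, rose 1.5-fold (edgeR adjusted p = 0.0411). That call was lost with limma voom (0.0681), with TPM (0.0766 and 0.0803), without both CCI contralateral libraries of animals 1 and 5 (0.0906), and when any of 8 single libraries was left out. For P2ry12 the edgeR adjusted p was 0.063, 0.0532 and 0.062 without CCI contralateral 1, 2 and 5, and 0.0843, 0.0834 and 0.0949 without CCI ipsilateral 1, 3 and 5. It was 0.0622 without sham contralateral 6 and 0.346 without sham ipsilateral 6.

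Of 12 monocyte and macrophage genes tested, 11 rose, also when adjusted over the list alone, with a median of 3.04 that stays the same with Arg1 at its bound (camera adjusted p = 1.1e-10). Ccr2 (ENSMUSG00000049103.11, chromosome 9, 124101950 to 124113557) had 2 counts in the sham ipsilateral and 112 in the CCI ipsilateral libraries, a ratio of 22.5 (95% counting interval 6.09 to 188; edgeR adjusted p = 7.07e-06). Each sham contralateral library had 4 counts of Ccr2, more than either sham ipsilateral one (0 and 2). Arg1, the arginase of alternatively activated macrophages, had 0 counts in both sham ipsilateral libraries and 8.97 ± 2.42 CPM in the CCI ipsilateral ones, at least 37.2-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 3.26e-09). Ly6c2, a marker of inflammatory monocytes that was too low to test, had 5, 4, 14 and 8 counts in the CCI ipsilateral libraries of animals 1, 2, 3 and 5, and 0 in both sham ipsilateral ones. All 14 complement genes rose, also when adjusted over the list alone (camera adjusted p = 3.99e-17), among them C1qa, a subunit of C1q, by 4.38-fold and the receptor gene C3ar1 by 10.9-fold. Of 19 phagocytosis and lysosome genes 18 rose, the same number when adjusted over the list alone (camera adjusted p = 1.5e-24), and Fcer1g, a signalling chain of Fc receptors, rose 5.62-fold.

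Interferon-stimulated genes rose as a group: 30 of 33 tested, 31 when adjusted over the list alone, with a median of 1.65 (camera adjusted p = 5.64e-15; adjusted p = 0.148 with an estimated correlation). Isg15, a ubiquitin-like modifier, rose 4.55-fold (log2 fold change 2.19 ± 0.35 SE, edgeR adjusted p = 2.19e-05), and the transcription factor gene Irf7 4.47-fold. Ifit3 rose 4.02-fold (edgeR adjusted p = 0.00272), with an adjusted p of 0.0684 when only the ipsilateral groups were fitted. The mean log2 CPM of the interferon-stimulated genes was 3.01, 3.27, 4.03 and 3.54 in the CCI ipsilateral libraries of animals 1, 2, 3 and 5, and 1.98 and 1.99 in the sham ipsilateral ones. Of 9 tested genes for interferons, their receptors and regulators, 4 rose, and 5 when adjusted over the list alone (camera adjusted p = 0.00148). The 4 members with the smallest p were Irf8, Tmem173, Irf5 and Ifngr1. Irf8, Tmem173 and Irf5 encode neither interferons nor their receptors, so the list's rise is not one of interferons or receptors alone. Ifnar1, a chain of the type I interferon receptor, had a log2 fold change of 0.11 ± 0.08 SE (edgeR adjusted p = 0.393). Counts of Ifnb1, encoding interferon beta, were 0 in the 13 libraries.

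Of 10 chemokine genes 7 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.0143; adjusted p = 0.0694 with an estimated correlation). Cxcl10, a chemokine induced by interferon, rose 15.9-fold, from 3 and 1 counts in the sham ipsilateral libraries of animals 4 and 6. Ccl2, a ligand of Ccr2, was at least 13.2-fold higher than in these libraries, which had 0 counts of it (edgeR adjusted p = 5.32e-05). In the authors' deposited DESeq2 comparison Cxcl10 was not called (log2 estimate 1.17, adjusted p = 0.385), whereas Ccl2 was (3.57, 0.0066). The median of 1.95 is the same with Ccl2 at its bound. The member that fell was Cx3cl1, a chemokine of neurons (log2 fold change -0.59, edgeR adjusted p = 7.27e-06). Of 13 inflammatory cytokine genes 11 rose, and 12 when adjusted over the list alone (camera adjusted p = 2.51e-08). Il1b and Tnf were too low to test, with 5, 3, 7 and 3 and 1, 1, 3 and 2 counts in the CCI ipsilateral libraries of animals 1, 2, 3 and 5, and 2 and 1 and 0 and 0 in the sham ipsilateral libraries of animals 4 and 6. MHC class II genes rose in 6 of 7 cases, also when adjusted over the list alone, with Cd74 at 4.53-fold and H2-Aa at 7.42-fold (camera adjusted p = 0.000108; adjusted p = 0.11 with an estimated correlation). MHC class I genes rose in 10 of 11, likewise when adjusted over the list alone, with B2m at 2.29-fold (camera adjusted p = 6.72e-08; adjusted p = 0.144 with an estimated correlation).

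Reactive astrocyte genes rose in 19 of 21 cases, 20 when adjusted over the list alone (camera adjusted p = 1.18e-17). Gfap (ENSMUSG00000020932.12, chromosome 11, 102887336 to 102900912), the intermediate filament of astrocytes, rose from 181.2 ± 19.6 CPM (n = 2) to 1461 ± 452 CPM (n = 4), 8.05-fold (log2 fold change 3.01 ± 0.31 SE, edgeR adjusted p = 9.92e-05). The protease inhibitor gene Timp1 had 1 count in sham and 267 in CCI libraries, a ratio of 107 (95% counting interval 19.1 to 4260). Homeostatic astrocyte genes rose in 8 of 13, 9 when adjusted over the list alone, with the water channel gene Aqp4 at 2.47-fold (camera adjusted p = 4.59e-06; adjusted p = 0.154 with an estimated correlation). Genes of extracellular matrix and scar rose in 17 of 21, 18 when adjusted over the list alone (camera adjusted p = 1.21e-13), with Tnc, encoding tenascin C, at 4.28-fold. Of 16 cell cycle genes 14 rose, 15 when adjusted over the list alone, with the topoisomerase gene Top2a at 12.5-fold (camera adjusted p = 1.72e-08; adjusted p = 0.129 with an estimated correlation). Axon injury genes rose in 5 of 10, 6 when adjusted over the list alone, with the stress-induced transcription factor gene Atf3 at 13.6-fold (camera adjusted p = 0.00693; adjusted p = 0.069 with an estimated correlation). Oligodendrocyte precursor genes rose in 4 of 9, 5 when adjusted over the list alone (camera adjusted p = 0.0022; adjusted p = 0.148 with an estimated correlation), with the receptor gene Gpr17 at 2.93-fold (edgeR adjusted p = 0.00349; 0.0509 without the sham ipsilateral library of animal 6).

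All 15 immediate early genes fell, also when adjusted over the list alone (camera adjusted p = 1.86e-17). Egr2, a zinc finger transcription factor, fell 4.62-fold (log2 fold change -2.21 ± 0.22 SE, edgeR adjusted p = 1.22e-08), Egr4 3.41-fold and the orphan nuclear receptor gene Nr4a1 2.86-fold. Egr1 fell 2.78-fold, from 289.4 ± 13.6 to 104.1 ± 15.9 CPM, and Fos 2.12-fold. Arc (ENSMUSG00000022602.12, chromosome 15, 74669083 to 74672570), which regulates synaptic receptors, fell 2.77-fold, from 216.2 ± 8.91 to 78 ± 12 CPM (edgeR adjusted p = 0.000417). Of 22 synaptic genes 18 fell, 19 when adjusted over the list alone (camera adjusted p = 6.6e-15), with Snap25, a protein of vesicle fusion, at 1.41-fold and the neurofilament gene Nefl at 1.43-fold. Of 16 excitatory neuron genes 12 fell, 13 when adjusted over the list alone (camera adjusted p = 1.67e-11), with Nrgn at 1.55-fold and Lamp5 at 1.82-fold. The mean log2 CPM of this list was 7.145 and 7.229 in sham ipsilateral libraries, above each contralateral library (6.918 to 7.064), which adds to its fall. Inhibitory neuron genes fell in 4 of 11, 5 when adjusted over the list alone, with the neuropeptide genes Cck and Sst at 1.72-fold and 1.48-fold (camera adjusted p = 0.0022; adjusted p = 0.148 with an estimated correlation). Cholesterol synthesis genes fell in 15 of 16, also when adjusted over the list alone (camera adjusted p = 3.66e-13; adjusted p = 0.0543 with an estimated correlation). Insig1, a regulator of sterol synthesis, fell 1.64-fold. Erdr1, whose reads can be shared between the X and Y chromosomes, was 2.63-fold lower (edgeR adjusted p = 0.00525; 0.0626 without the sham ipsilateral library of animal 4).

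Markers of other cells and regions moved in the same comparison. Camera called lists lower for the striatum (4 of 12 genes fell, also when adjusted over the list alone; adjusted p = 0.000461), the thalamus (5 of 9, also over the list alone; 0.00889), the hippocampus (4 of 9 fell; 6 fell and 1 rose when adjusted over the list alone; 0.00515) and mitochondrially encoded genes (7 of 13, 9 when adjusted over the list alone; 5.2e-06). With an estimated correlation their adjusted p were 0.154, 0.22, 0.0793 and 0.182. Camera called lists higher for mature oligodendrocytes (6 of 13 rose, also when adjusted over the list alone; adjusted p = 0.00149), meningeal fibroblasts (4 of 12, 6 when adjusted over the list alone; 0.00164), endothelium (5 of 12, also over the list alone; 0.025), ependyma (2 of 8, also over the list alone; 0.0394), neutrophils (1 of 4, also over the list alone; 0.0477) and hypothalamus (0 of 11 by edgeR, also over the list alone; 0.0394). With an estimated correlation their adjusted p were 0.148, 0.185, 0.304, 0.175, 0.148 and 0.439. The calls for thalamus (0.0735 without sham ipsilateral 4), endothelium (0.14), ependyma (0.0977), neutrophils (0.146) and hypothalamus (0.436, each without sham ipsilateral 6) depended on single libraries. Endothelium also lost its call without CCI ipsilateral 5 (0.0695), ependyma without CCI ipsilateral 1 (0.0566), and hypothalamus without CCI ipsilateral 1 (0.0915) or 2 (0.0808). Neutrophils also lost theirs without CCI contralateral 1 (0.0503), sham contralateral 6 (0.0521) or 8 (0.0501) or CCI ipsilateral 3 (0.0523).

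In total camera called 32 of 44 lists in this comparison. With an estimated correlation 11 held: activated microglia, monocytes and macrophages, complement, phagocytosis and lysosome, inflammatory cytokines, interferon receptors and regulators, reactive astrocytes, matrix and scar, excitatory neurons, synapses and immediate early genes, at adjusted p of 0.0176 to 0.0486. Lists not called included T and NK cells, of which 2 of 4 genes fell, also when adjusted over the list alone (camera adjusted p = 0.239), B cells (0.239), angiogenesis and hypoxia (0.773), pericytes (0.0684), glucocorticoid response (0.405), heat shock (0.129), olfactory bulb (0.854), midbrain and hindbrain (0.251) and skeletal muscle (0.904). Angiogenesis and hypoxia genes moved both ways. Hmox1, Angpt2, Hif1a and Pdk1 rose (edgeR adjusted p of 2.12e-06 to 0.0359), Vegfa, Apln and Bnip3 fell (5.19e-07 to 0.0296), and the others did not pass. Some lists gained a call when 1 library was left out: heat shock, lower, without CCI ipsilateral 1 (0.012), pericytes, higher, without sham ipsilateral 4 (0.0219) and red blood cells, lower, without sham ipsilateral 6 (0.0361). In 3 lists not called, median and test differed in sign. These were red blood cells (median -0.02, mean -0.08, higher by camera, adjusted p = 0.984), cerebellum (median 0.16, mean 0.12, lower, 0.74) and choroid plexus (median 0.02, mean -0.03, lower, 0.882).

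**Figure D2:**
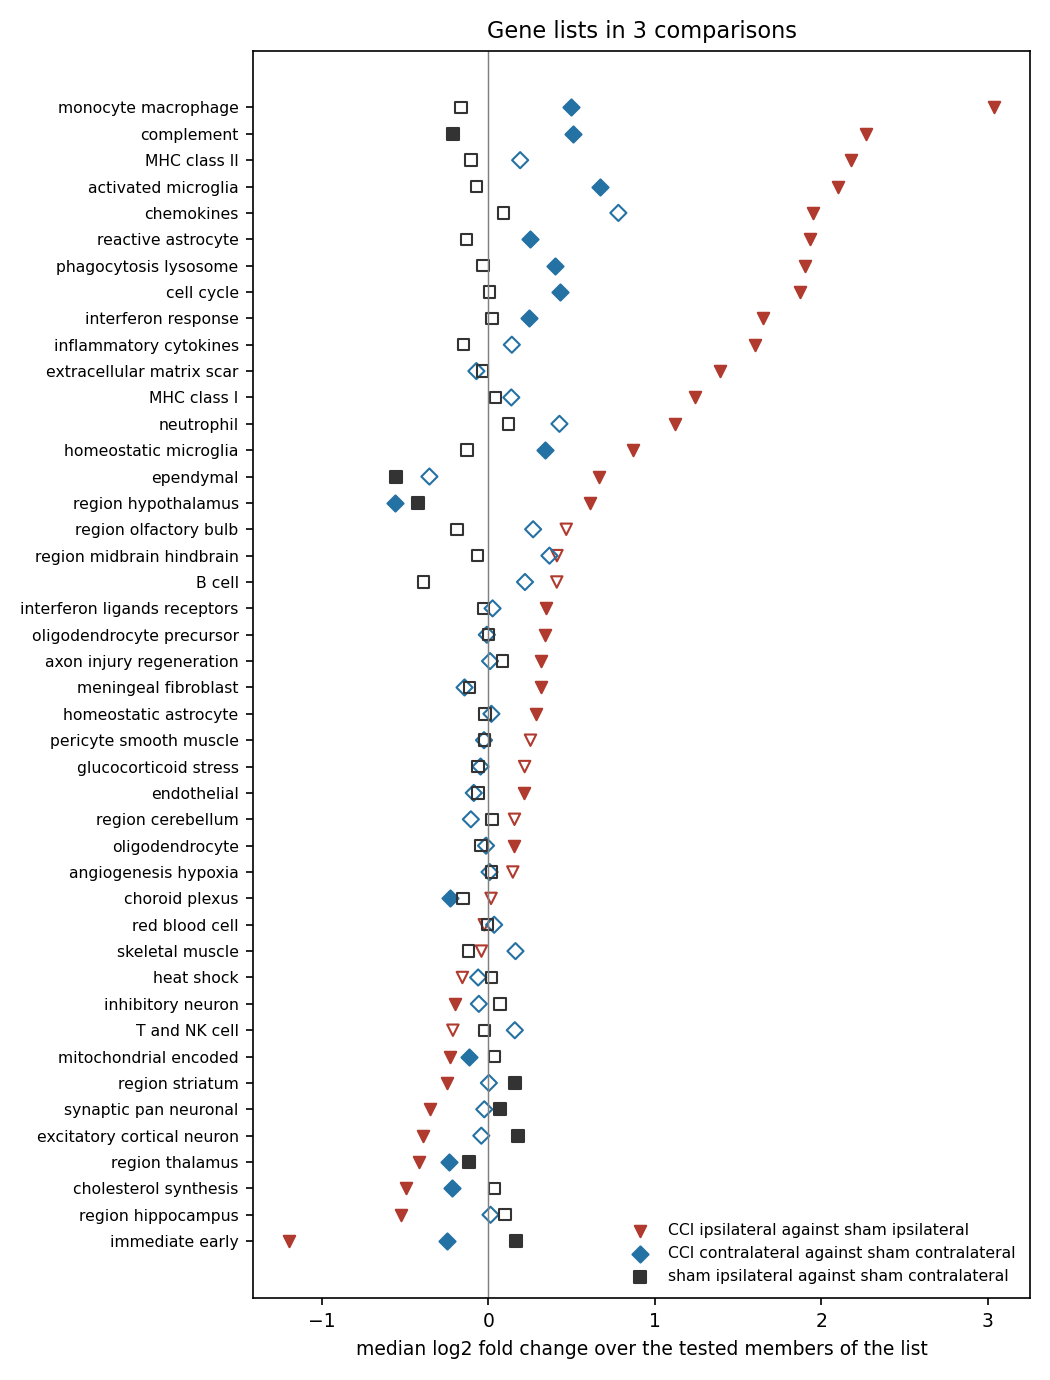
Median log2 fold change over the tested members of each gene list (x axis) for the 44 lists (y axis) in CCI against sham in the ipsilateral (triangles) and contralateral (diamonds) hemisphere and in sham ipsilateral against contralateral (squares); filled symbols are lists called by camera with the preset correlation. Ipsilateral medians run from -1.20 for immediate early genes to 3.04 for monocyte and macrophage genes.

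In the contralateral hemisphere, CCI was compared with sham to see whether tissue away from the impact differed. By edgeR 2 of 22 activated microglia genes, 2 of 14 complement genes and 1 of 21 reactive astrocyte genes rose there, and 0 of 14 homeostatic microglia genes. Camera called these 4 lists higher with the preset correlation, but not with an estimated one (adjusted p = 0.248, and 0.324 for reactive astrocytes), and fry called none of them. Serpina3n (ENSMUSG00000021091.8, chromosome 12, 104406729 to 104414329), a protease inhibitor of reactive astrocytes, rose 3.41-fold from 17.6 ± 1.24 CPM (n = 3) to 59.6 ± 11 CPM (n = 4; log2 fold change 1.77 ± 0.20 SE, edgeR adjusted p = 0.0215). A2m, the protease inhibitor alpha-2-macroglobulin, rose 2.57-fold (edgeR adjusted p = 2.79e-05), and Cd180, a receptor of the toll-like family, 3.43-fold (edgeR adjusted p = 0.0164). At an edgeR adjusted p of 0.0418 rose the complement gene C4b (2.43-fold), C1qa (1.61-fold), Cd68 (1.81-fold), the surface glycoprotein gene Cd52 (3.33-fold), the Fc receptor gene Fcgr2b (2.01-fold) and the lysosomal protease gene Ctsl (1.31-fold). At the same adjusted p the imprinted gene Peg10 fell 1.39-fold and Vegfa, the vascular growth factor, 1.29-fold. Both lost their call with log2(TPM + 1) (limma adjusted p = 0.13 and 0.46) and log2(TPM + 0.1) (0.126 and 0.437), where the 19 and 15 genes called were all higher, and Vegfa also with median-of-ratios scaling (edgeR adjusted p = 0.0515). Cd52 and Ctsl lost theirs with TPM too, each at 0.0864 and 0.082.

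In all 12 genes rose and 2 fell contralaterally, and 1021 genes had an unadjusted p under 0.05 where chance gives 744. The 12 were all also higher in the ipsilateral comparison, where 1.5 would be shared by independent lists, and of the 2 that fell Peg10 was not called lower ipsilaterally. The 2 comparisons share no library, and their animals are the same except sham animal 8, which has only a contralateral library here. The count of 14 became 37 with DESeq2, 1 with limma voom, 106 without a filter, 41 when only the contralateral groups were fitted and 9 without the CCI contralateral libraries of animals 1 and 5, of which 5 were among the 14. In that fit calls were lost for Serpina3n (edgeR adjusted p = 0.0726), Cd68 (0.0757), Fcgr2b (0.112), Ctsl (0.161), C4b (0.165), Vegfa (0.187) and Peg10 (0.206). With limma voom the named genes other than A2m had adjusted p of 0.0878 (Serpina3n) to 0.303 (Cd52). The count was 1 without sham contralateral 4 or 6 and 5 without sham contralateral 8. It was 6, 3 and 7 without CCI contralateral 2, 3 and 5, and 4 without either sham ipsilateral library, and 34 without CCI ipsilateral 2 and 24 without CCI ipsilateral 3. A2m kept its call under each alternative. Without the sham contralateral library of animal 4, the other 10 genes named above had edgeR adjusted p from 0.148 (Serpina3n, Ctsl) to 0.349 (Vegfa), and without that of animal 6 from 0.17 (Serpina3n, Cd180) to 0.258 (C1qa). Of these 10, calls were also lost for 9 without CCI contralateral 3 (0.0564 for Cd180 to 0.213 for Vegfa), 8 without CCI contralateral 5 (0.0668 for Ctsl to 0.0934 for C4b), 7 without CCI contralateral 2 (0.0597 for Ctsl to 0.151 for Peg10) and 5 without CCI contralateral 1 (0.0523 for Fcgr2b to 0.111 for Peg10). They were lost for 7 without sham contralateral 8 (0.0592 for C1qa to 0.199 for Ctsl), and for 8 without sham ipsilateral 4 (0.0653 for Cd68 to 0.097 for C4b) or 6 (0.0659 for Serpina3n to 0.0966 for C4b). C4b also lost its call without CCI ipsilateral 1 (0.0722) or 5 (0.0526), and Vegfa without CCI ipsilateral 1 (0.0597). The authors' deposited table calls 28 genes higher and 5 lower here, 8 of them shared with these 14.

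Of the 22 fixed genes tested, Cd68 and C1qa rose contralaterally and 20 did not pass. Over all 22, Cd68 and C1qa included, 10 had an unadjusted edgeR p under 0.05. Gfap was at 546.7 ± 71.5 CPM in CCI (n = 4) and 191.6 ± 32.3 CPM in sham (n = 3), a log2 difference of 1.51 ± 0.25 SE with an edgeR adjusted p of 0.105. Gfap was called by DESeq2 (adjusted p = 2.53e-07), without a filter (0.0491), in a fit of only these groups (0.0447), with log2(TPM + 1) (0.0478) and without CCI ipsilateral 2 (0.045). Trem2 had a log2 fold change of 0.86 ± 0.23 SE (edgeR adjusted p = 0.379), C3 1.43 ± 0.44 (0.438), Spp1 0.79 ± 0.29 (0.633), Gpnmb 1.495 ± 0.63 (0.7) and Ccr2 0.83 ± 0.495 (0.8). Trem2 was called by DESeq2 (adjusted p = 0.00349), without a filter (1.35e-07) and in a fit of only these groups (0.00908), Gpnmb by DESeq2 (0.0281) and in a fit of only these groups (0.00275), and C3 without a filter (0.00657) and without CCI contralateral 1 and 5 (0.0378). Isg15 had -0.03 ± 0.33 (0.999), Ifit3 0.69 ± 0.34 (0.771; 0.0208 in a fit of only these groups) and Irf7 0.99 ± 0.41 (0.642). Cxcl10 rested on 15 counts against 2, a ratio of 5.54 (95% counting interval 1.29 to 49.9), and Ccl2 on 7 against 2, a ratio of 2.59 (0.492 to 25.5). The remaining fixed genes, Tmem119, P2ry12, Cx3cr1, Itgam, Aif1, Apoe, Cd74, Arg1 and Ifnar1, had log2 fold changes of 0.03 (Ifnar1) to 0.60 (Aif1).

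Camera called 14 lists contralaterally, of which 0 held with an estimated correlation and 0 were called by fry. Higher lists were activated microglia (2 of 22 genes rose, 14 when adjusted over the list alone; median 0.67, the same with Cst7, at 0 counts in sham, at its bound; camera adjusted p = 1.57e-19), phagocytosis and lysosome (2 of 19, 9 over the list alone; 4.05e-14), homeostatic microglia (0 of 14, 6 over the list alone; 9.83e-11) and complement (2 of 14, 6 over the list alone; 8.6e-09). For each of these 4 lists the adjusted p was 0.248 with an estimated correlation. Reactive astrocyte genes (1 of 21, 4 when adjusted over the list alone; camera adjusted p = 6.15e-07) had an adjusted p of 0.324 with an estimated correlation. Interferon-stimulated genes (0 of 33, also when adjusted over the list alone; median 0.25; camera adjusted p = 0.00011), monocyte genes (0 of 12, also over the list alone; 0.00136) and cell cycle genes (0 of 16, also over the list alone; 0.00177) had adjusted p of 0.634, 0.429 and 0.6 with an estimated correlation. The monocyte list was not called without sham contralateral 4 (0.0865).

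Lists called lower contralaterally were cholesterol synthesis (0 of 16 by edgeR, 9 when adjusted over the list alone; median -0.22; camera adjusted p = 1.1e-11), hypothalamus (0 of 11, 3 over the list alone; median -0.56; 4.9e-10), immediate early genes (0 of 15, 2 over the list alone; median -0.25; 9.12e-08) and thalamus (0 of 9, 3 over the list alone; 9.77e-06). Their adjusted p were 0.248, 0.248, 0.252 and 0.248 with an estimated correlation. Mitochondrially encoded genes (0 of 13, also when adjusted over the list alone; camera adjusted p = 9.77e-06) and choroid plexus genes (0 of 11, also over the list alone; 0.000899) had adjusted p of 0.429 and 0.265 with an estimated correlation. The choroid plexus list was not called without sham contralateral 8 (0.0804) or without CCI contralateral 1 and 5 (0.0558). Sim1, a hypothalamic transcription factor, was at 0.41 ± 0.183 CPM in CCI and 1.31 ± 0.204 CPM in sham contralateral libraries (edgeR adjusted p = 0.35). In 3 lists not called, signs differed: angiogenesis and hypoxia (median 0.0072, mean -0.015, lower by camera, adjusted p = 0.484), cerebellum (median -0.11, mean 0.23, lower, 0.484) and oligodendrocytes (median -0.014, mean 0.0065, higher, 0.918). The cerebellum list was called lower without CCI contralateral 3 (0.0341). The axon injury list was not called (lower by camera, adjusted p = 0.486), with a median of -0.0019 and a mean of -0.052 with the member at 0 counts at its bound.

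**Figure D3:**
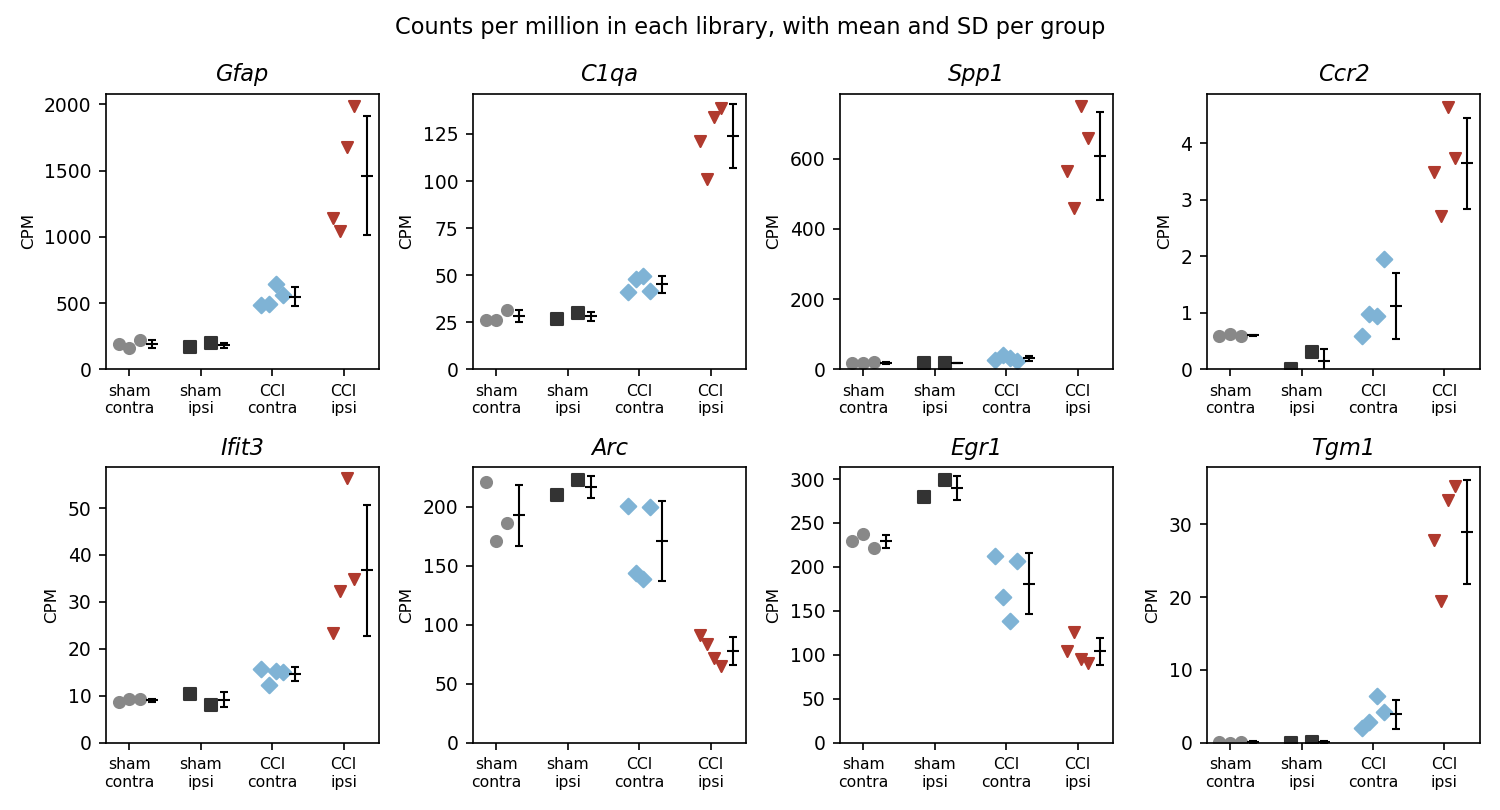
CPM (y axis, linear, from 0) of Gfap, C1qa, Spp1, Ccr2, Ifit3, Arc, Egr1 and Tgm1 in each of the 13 libraries, by group, with the group mean and SD as a bar beside the points. Gfap has means of 191.6, 181.2, 546.7 and 1461 CPM in sham contralateral, sham ipsilateral, CCI contralateral and CCI ipsilateral libraries, and Arc falls to 78 CPM in the last group.

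Within the injured mice, the ipsilateral hemisphere was compared with the contralateral one of the same animals. By the sample names this is also right against left, so this comparison alone does not separate impact from side. Again macrophage, activated microglia, matrix and astrocyte genes were higher on the side of impact, and immediate early and synaptic genes lower. The immediate early list had an adjusted p of 0.0624 with an estimated correlation. Gpnmb was 20.2-fold higher (160.9 ± 51.3 against 7.83 ± 2.69 CPM, SD, n = 4 each), Lgals3 19.9-fold, Spp1 19.5-fold and Lyz2 18.9-fold. Hmox1 was 16.3-fold higher, Atf3 12.3-fold and Lcn2, the iron-binding lipocalin 2, 8.88-fold. Gucy1a2, a subunit of soluble guanylate cyclase, was 2.63-fold lower (log2 fold change -1.39 ± 0.17 SE, edgeR adjusted p = 5.39e-06), Abhd12b 2.49-fold, the NMDA receptor gene Grin2a 2.48-fold, Nr4a1 2.26-fold, Arc 2.18-fold and the activity-dependent transcription factor gene Npas4 2.15-fold.

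Between the hemispheres of CCI mice, 1909 genes were higher and 1324 lower ipsilaterally, 543 and 28 of them by at least 2-fold. With limma on log2(TPM + 1) these were 1758 and 602, a share of higher genes of 74.5% instead of 59%. The authors' deposited table calls 1125 higher and 349 lower. Of the 22 fixed genes, 21 were higher. Arg1 was 32.4-fold higher (log2 fold change 5.02 ± 0.37 SE, edgeR adjusted p = 5.15e-11), Cxcl10 9.39-fold, Ccl2 11.4-fold, Ccr2 3.32-fold, Cd68 4.78-fold, C1qa 2.74-fold, C3 3.79-fold and Gfap 2.67-fold. Isg15, Irf7 and Ifit3 were 3.45-fold, 3.36-fold and 2.51-fold higher, and Cd74, Trem2, Aif1 and Apoe 4.63-fold, 2.34-fold, 2.2-fold and 1.5-fold. Without the CCI contralateral libraries of animals 1 and 5, calls were lost for Tmem119 (1.39-fold, edgeR adjusted p = 0.00499, then 0.0649), Cx3cr1 (1.66-fold, 0.0114, then 0.0911) and Itgam (2.02-fold, 0.00521, then 0.0635). Ifnar1 (1.16-fold, edgeR adjusted p = 0.0175) lost its call in that fit (0.0919), with DESeq2 (0.0563) and without CCI contralateral 1 (0.0839) or 2 (0.0573) or CCI ipsilateral 3 (0.0559). P2ry12 did not pass (log2 fold change 0.26 ± 0.14 SE, edgeR adjusted p = 0.241) but did with the animal as a block (0.0155), without a filter (0.0192) and without CCI ipsilateral 2 (0.0152).

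Activated microglia genes were higher in 22 of 22 cases, also when adjusted over the list alone (camera adjusted p = 2.66e-29), phagocytosis and lysosome genes in 19 of 19, likewise (1.08e-25), and matrix and scar genes in 19 of 21, likewise (9.01e-18). Reactive astrocyte genes were higher in 19 of 21, 21 when adjusted over the list alone (camera adjusted p = 1.03e-18), with the membrane protein gene Emp1 at 5.29-fold. Interferon-stimulated genes were higher in 32 of 33, also when adjusted over the list alone, with Bst2 at 3.84-fold and Ifitm3 at 2.38-fold (camera adjusted p = 2.91e-18; adjusted p = 0.113 with an estimated correlation). Cell cycle genes were higher in 15 of 16, 16 when adjusted over the list alone (camera adjusted p = 2.11e-10; adjusted p = 0.0886 with an estimated correlation). Oligodendrocyte precursor genes were higher in 8 of 9, 9 when adjusted over the list alone (camera adjusted p = 7.91e-06; adjusted p = 0.0683 with an estimated correlation). Synaptic genes were lower in 15 of 22, 18 when adjusted over the list alone (camera adjusted p = 2.64e-11). Immediate early genes were lower in 13 of 15, 14 when adjusted over the list alone (camera adjusted p = 1.08e-11; adjusted p = 0.0624 with an estimated correlation), and cholesterol synthesis genes in 9 of 16, 13 over the list alone (8.75e-08; adjusted p = 0.133 with an estimated correlation).

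Hypothalamic genes were higher ipsilaterally in CCI mice in 2 of 11 cases, 6 when adjusted over the list alone, with Sim1 at 4.45-fold (camera adjusted p = 0.00021; adjusted p = 0.234 with an estimated correlation). Of 4 T and NK cell genes tested 2 were lower, also when adjusted over the list alone, among them Trbc2, a T cell receptor segment, by 2.07-fold (camera adjusted p = 0.0177, and 0.133 with an estimated correlation). The list's mean ran from 3.569 to 4.221 log2 CPM over all libraries, sham ones included. Whether its reads come from T or NK cells was not tested, so a fall of these cells is not shown. The neutrophil list (2 of 4 genes higher, also when adjusted over the list alone; camera adjusted p = 0.0201; adjusted p = 0.112 with an estimated correlation) lost its call with the animal as a block (0.0694) and without CCI contralateral 1 and 5 (0.0877). Camera called 32 of the 44 lists, and 12 held with an estimated correlation. These were activated microglia, monocytes and macrophages, complement, phagocytosis and lysosome, chemokines, inflammatory cytokines, interferon receptors and regulators, reactive astrocytes, matrix and scar, axon injury, synapses and hippocampus, at adjusted p of 0.0298 to 0.0491. Signs differed for heat shock (median -0.06, mean 0.07, lower by camera, adjusted p = 0.762), red blood cells (median 0.03, mean -0.08, lower, 0.688), midbrain and hindbrain (median 0.05, mean -0.02, higher, 0.504) and olfactory bulb (median 0.0090, mean -0.05, lower, 0.575), none of them called.

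In sham mice, ipsilateral and contralateral hemispheres were compared as the control for the hemisphere itself. Camera with the preset correlation called 8 lists, among them cortical excitatory neurons higher ipsilaterally and ependyma and hypothalamus lower. With an estimated correlation 0 lists held (adjusted p = 0.205, 0.422 and 0.937 for these 3), fry called 0, and the ependymal and hypothalamic calls were lost without sham ipsilateral 6 (0.141 and 0.755). The only gene called was Rpl37a (ENSMUSG00000046330.9, chromosome 1, 72711290 to 72713813), a ribosomal protein gene, at 87.8 ± 9.07 CPM ipsilaterally (n = 2) and 121.3 ± 9.88 CPM contralaterally (n = 3; log2 fold change -0.47 ± 0.08 SE, edgeR adjusted p = 0.0276). Its call was lost with log2(TPM + 1) (0.142) and log2(TPM + 0.1) (0.0764), and without CCI contralateral 2 (0.0501), sham contralateral 4 (0.209) or 8 (0.124) or sham ipsilateral 6 (1). Ribosomal protein genes have many processed copies, so its reads may be divided among them. An unadjusted p under 0.05 was reached by 908 genes, where chance gives 744. DESeq2 called 4 genes, limma voom 1, edgeR without a filter 26 and edgeR on the sham groups alone 23. With the animal as a block, 303 genes were called from 2 pairs with 1 residual degree of freedom, and 5 when the 6 paired animals were fitted together. The count was 8 without sham contralateral 6, 3 without CCI ipsilateral 5 and 2 without CCI contralateral 1 or sham ipsilateral 4.

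Of the 22 fixed genes 0 passed between the sham hemispheres, by edgeR, DESeq2 and limma voom, and 0 had an unadjusted p under 0.05; the smallest edgeR adjusted p was 0.815 (Ccr2). Gfap had a log2 fold change of -0.08 ± 0.31 SE, C1qa 0.0057 ± 0.16, Spp1 -0.08 ± 0.40, Cd68 -0.10 ± 0.24 and Ifit3 0.01 ± 0.45. Fitted values over the 22 ran from -3.6 for Arg1, at 0 counts ipsilaterally, to 1.53 for Cxcl10. Cxcl10 had 3 and 1 counts ipsilaterally and 0, 1 and 1 contralaterally. Camera called excitatory neuron genes higher (median 0.18, 0 of 16 by edgeR, 6 when adjusted over the list alone; adjusted p = 3.97e-11; adjusted p = 0.205 with an estimated correlation). Rorb, Slc17a7 and Tbr1 of that list had log2 fold changes of 0.36, 0.20 and 0.25, and passed with the animal as a block in the fit of 2 pairs with 1 residual degree of freedom (edgeR adjusted p = 0.0251, 0.000302 and 0.0447). They did not pass with the 6 paired animals fitted together (0.165, 0.174 and 0.252). Striatal (0 of 12, also when adjusted over the list alone; camera adjusted p = 0.000114), synaptic (0 of 22, 1 over the list alone; 0.000325) and immediate early genes (0 of 15, also over the list alone; 0.000641) were also called higher, with adjusted p of 0.503, 0.422 and 0.782 with an estimated correlation. Hypothalamic (0 of 11, also when adjusted over the list alone; camera adjusted p = 0.00405), ependymal (0 of 8, 1 over the list alone; 0.00535), complement (0 of 14, 1 over the list alone; 0.032) and thalamic genes (0 of 9, also over the list alone; 0.032) were called lower, with adjusted p of 0.937, 0.422, 0.977 and 0.937 with an estimated correlation.

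The calls for synapses (0.132), hypothalamus (0.755), ependyma (0.141), complement (0.433) and thalamus (0.634) were lost without sham ipsilateral 6, and those for complement (0.433) and thalamus (0.397) without sham contralateral 8. With the animal as a block, complement (0.441), thalamus (0.0636) and ependyma (0.0596) were not called. The mitochondrially encoded list was (camera adjusted p = 0.0059), which had an adjusted p of 0.704 without the block and 0.258 with the 6 paired animals fitted together. It was called higher without sham ipsilateral 4 (0.000243) and lower without sham ipsilateral 6 (0.00236). Among lists not called, signs differed for interferon-stimulated genes (median 0.02, mean -0.0055, higher by camera, adjusted p = 0.811), MHC class I (median 0.04, mean -0.02, lower, 0.96), MHC class II (median -0.10, mean -0.14, higher, 0.96), matrix (median -0.04, mean 0.0022, lower, 0.946), inhibitory neurons (median 0.07, mean -0.0030, higher, 0.55), pericytes (median -0.02, mean -0.02, higher, 0.96), red blood cells (median -0.0055, mean 0.16, lower, 0.96; called higher without sham ipsilateral 6, 0.00236) and cerebellum (median 0.02, mean -0.09, lower, 0.948).

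The last comparison tested whether the hemisphere effect differed between CCI and sham mice. This takes out a difference between hemispheres that both treatments share, but adds any departure of the 2 sham ipsilateral libraries. Mean log2 CPM of excitatory neuron genes was 7.145 and 7.229 in sham ipsilateral and 6.922 to 7.041 in sham contralateral libraries. It was 6.682 to 6.785 in CCI ipsilateral and 6.918 to 7.064 in CCI contralateral libraries, so part of that list's difference lies in sham. The hemisphere effect was higher in CCI mice for 12 of 14 complement genes, 15 of 22 activated microglia genes and 12 of 21 matrix and scar genes. It was lower for 10 of 15 immediate early, 10 of 22 synaptic and 10 of 16 excitatory neuron genes. Of 12 monocyte and macrophage genes 8 had a higher effect, 9 when adjusted over the list alone (camera adjusted p = 1.36e-08; adjusted p = 0.0709 with an estimated correlation). The excess was 41.1-fold for Lgals3 (log2 5.36 ± 0.68 SE, edgeR adjusted p = 9.4e-06), 21.2-fold for Hmox1, 20.6-fold for Spp1, 5.11-fold for Cd68 (edgeR adjusted p = 9.22e-07), 5.02-fold for Tnc and 2.73-fold for C1qa. It was 3.02-fold downward for Egr2 (log2 -1.59 ± 0.29 SE, edgeR adjusted p = 0.000913) and 2.41-fold for Nr4a1. In all 720 genes had a higher and 445 a lower effect, 360 and 16 by at least 2-fold. With log2(TPM + 1) these were 632 and 164, a share of 79.4% instead of 61.8%, and without sham ipsilateral 6 the count of 1165 became 392. With log2(TPM + 0.1) it was 721.

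Of the 22 fixed genes 12 had a higher effect and 10 did not pass, with 18 at an unadjusted p under 0.05. Calls for Lyz2 (23-fold, edgeR adjusted p = 0.00444), Gpnmb (18.6-fold, 0.0399), C3 (8.47-fold, 0.0224), Gfap (2.82-fold, 0.0434), Arc (2.45-fold lower, 0.0154) and Egr1 (2.19-fold lower, 0.0163) were lost with the animal as a block, at 0.0656, 0.128, 0.139, 0.0854, 0.0816 and 0.0936. Gpnmb also lost its call with limma voom (0.0566), without a filter (0.0505) and without CCI contralateral 1 and 5 (0.107), Gfap in the latter fits (0.0552 and 0.131), and C3 with limma voom (0.0604). Trem2 (edgeR adjusted p = 0.0516), Cx3cr1 (0.109) and Itgam (0.12) passed with the block, at 0.00384, 0.00163 and 0.00305. Isg15 had a 4.64-fold larger effect (edgeR adjusted p = 0.00476), while Irf7 (2.25-fold, 0.268) and Ifit3 (2.48-fold, 0.173) did not pass. Ifit3 did pass with DESeq2 (0.0364), with TPM (0.0444 and 0.0457) and without CCI ipsilateral 1 (0.0201) or 3 (0.0061). Apoe had a 1.66-fold larger effect (edgeR adjusted p = 5.6e-05). Arg1 passed (edgeR adjusted p = 0.00265; 0.108 without sham contralateral 4), but with 0 counts in sham ipsilateral libraries no fold is given. Ccl2, at 0 there too, did not pass (0.139; 0.0418 with limma voom and 0.00555 with log2(TPM + 1)). Cxcl10 (0.632; 0.0357 with log2(TPM + 1)), Tmem119 (0.172), P2ry12 (0.57) and Ifnar1 (0.732) did not pass either.

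Single libraries decided further calls of this difference. Without sham ipsilateral 6 calls were lost for Arc (edgeR adjusted p = 0.0857), Egr1 (0.0914), Aif1 (2.67-fold, 0.00645, then 0.107), Cd74 (3.67-fold, 0.00362, then 0.0508) and Abhd12b (2.3-fold lower, 0.0175, then 0.053). Abhd12b also lost its call without sham contralateral 4 (0.057) or sham ipsilateral 4 (0.0942), and Ccr2, which rests on 2 counts in sham ipsilateral libraries (edgeR adjusted p = 0.0161), without sham ipsilateral 4 (0.0929) and with DESeq2 (0.053). C3 lost it without sham contralateral 4 (0.0902) or 6 (0.0783) or sham ipsilateral 4 (0.0525) or 6 (0.177). Gpnmb lost its call without CCI contralateral 1 (0.0719), 3 (0.0619) or 5 (0.059), sham contralateral 4 (0.128), 6 (0.083) or 8 (0.109), CCI ipsilateral 5 (0.0614) or sham ipsilateral 4 (0.096) or 6 (0.119). Gfap lost it without CCI contralateral 1 (0.0804), 2 (0.0785) or 5 (0.063), sham contralateral 4 (0.088) or 8 (0.104), CCI ipsilateral 3 (0.072) or 5 (0.0513) or sham ipsilateral 4 (0.139) or 6 (0.14). Trem2 gained a call without CCI contralateral 3 (0.0204), sham contralateral 4 (0.0186) or any CCI ipsilateral library (0.0336, 0.0045, 0.047 and 0.0495 for 1, 2, 3 and 5), Cx3cr1 without sham contralateral 4 (0.0352) and Itgam without CCI ipsilateral 2 (0.00867). Snap25 (1.39-fold lower, edgeR adjusted p = 0.00058), Lamp5 (1.7-fold lower, 0.000728), Serpina3n (4.18-fold higher, 0.00432) and Ctsb (1.85-fold higher, 2.63e-07) kept theirs in each fit.

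Camera called 30 lists for the difference, and 9 held with an estimated correlation, at adjusted p of 0.0335 to 0.0458. These were activated microglia (15 of 22 genes higher, 19 when adjusted over the list alone), complement (12 of 14, 14 over the list alone), matrix and scar (12 of 21, 17 over the list alone), interferon receptors and regulators (4 of 9, also over the list alone), axon injury (3 of 10, also over the list alone), and, lower, immediate early genes (10 of 15, 14 over the list alone), synapses (10 of 22, 18 over the list alone), excitatory neurons (10 of 16, 12 over the list alone) and hippocampus (1 of 9, 4 over the list alone and 1 higher). The excitatory neuron list was not among the 12 that held between the hemispheres of CCI mice. Interferon-stimulated genes had a larger effect in 10 of 33, 16 when adjusted over the list alone (camera adjusted p = 5.31e-10; adjusted p = 0.215 with an estimated correlation). Phagocytosis and lysosome genes did in 16 of 19, 18 when adjusted over the list alone (camera adjusted p = 1.72e-21; adjusted p = 0.0503 with an estimated correlation), and reactive astrocyte genes in 15 of 21, 19 over the list alone (4.35e-15; adjusted p = 0.0503 with an estimated correlation). The pericyte list (camera adjusted p = 0.0208; adjusted p = 0.228 with an estimated correlation) was not called with the animal as a block (0.0811), without sham contralateral 8 (0.114) or without sham ipsilateral 6 (0.15). The mitochondrially encoded list was called lower (0 of 13 genes by edgeR, also when adjusted over the list alone; camera adjusted p = 0.00449; adjusted p = 0.424 with an estimated correlation), but not without sham ipsilateral 6 (0.659) or without CCI contralateral 1 and 5 (0.0642). In the olfactory bulb list, not called, median and mean were 0.13 and 0.23 and camera gave a lower direction (adjusted p = 0.936).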

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

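All tests of explanations and the counts over other splits of the libraries were chosen after the results were seen.

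In the contralateral hemisphere, 57 members of the microglial and reactive astrocyte lists had a median log2 fold change of 0.379 after CCI. By edgeR 2 of 22 activated microglia, 0 of 14 homeostatic microglia and 1 of 21 reactive astrocyte genes passed, and the lists lost their camera calls with an estimated correlation (adjusted p = 0.248, 0.248 and 0.324) and had none by fry. Material carried over from the ipsilateral side would bring its abundant transcripts in like proportion. The median share of the ipsilateral rise seen contralaterally was 17.3% for 18 activated microglia genes (2.17 to 37.6). It was -2.75% for 13 matrix and scar genes (-8.21 to 4.27), which argues against carry-over as the whole cause. The permutation p of this difference was 2e-05, but genes and not animals were exchanged. That p does not measure variation between animals. The medians of 10000 random lists matched on length, GC content and expression ran from -0.0704 to 0.0767, below the 0.379 observed. The microglial and astrocyte lists had been picked for their calls, and random members were drawn independently, without the correlation within a cell type. The comparison therefore bears on length, GC content and expression only, and not on whether the lists rose beyond chance. Tissue near the midline that lacks scar may still contribute, and a response of the uninjured hemisphere to the injury stays open as a hypothesis.

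Immediate early genes were lower in the ipsilateral hemisphere after CCI, with a median of -1.2 over 15 genes. Loss or dilution of neurons alone is argued against by the median of -0.358 over 38 synaptic and excitatory neuron genes, a difference of -0.845. The one-sided permutation p was 1e-05, the smallest the resamples can give. That permutation exchanged genes and not animals. Its p treats the genes of a list as independent and does not measure variation between animals. Handling at death that acts on the whole animal is argued against, as the whole cause, by the list's call in the difference of the hemisphere effects. The list's camera adjusted p of 0.0457 with an estimated correlation lies near the threshold. Arc and Egr1 lose that call with the animal as a block (edgeR adjusted p = 0.0816 and 0.0936). Camera with the preset correlation also called the list lower contralaterally after CCI, so a part shared by both hemispheres stays open. The list's mean log2 CPM was 5.201 and 5.211 in sham ipsilateral and 4.939 to 5.044 in sham contralateral libraries, which adds to the difference. The medians of 10000 matched random lists ran from -0.319 to 0.314. Random members were drawn independently, so this bears on length, GC content and expression only. Lower neuronal activity in the injured hemisphere is a hypothesis that these data do not test, and loss of those neurons that express these genes most may also contribute.

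The hypothalamus list was called lower in CCI than in sham contralateral libraries by camera with the preset correlation (adjusted p = 4.9e-10, median -0.559), but not with an estimated correlation (adjusted p = 0.248) or by fry (0.261), and 0 of its 11 genes passed by edgeR, 3 when adjusted over the list alone. The list mean was lowest in the CCI contralateral library of animal 1, at 1.05 log2 CPM. Without that library the camera adjusted p with the preset correlation was 5.18e-06 and the median -0.415. That library is therefore not the only source of the preset-correlation call. With an estimated correlation camera did not call the list with that library or without it (adjusted p = 0.357 without). Whether the list is lower beyond the spread of libraries is thus not settled. A midline cut that left more hypothalamus on the ipsilateral side of CCI animals cannot be told apart from a change in the tissue: both hemispheres summed differed by -0.0539 between CCI and sham animals (exact permutation p = 0.667, two-sided), and the 15 regroupings allow no p under 0.0667. The choice of libraries without animals 1 and 5 was made after seeing these values.

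For the 14 genes called contralaterally between CCI and sham, 1 of 35 splits of the 7 libraries gave as many, the real one. The highest other gave 8. That is the smallest share these splits can give, and they were counted after the 14 calls were seen. The count itself was 1 with limma voom, so the splits do not exclude chance. For the 3233 genes between the hemispheres of CCI animals, 1 of 35 splits gave as many and the highest other gave 4. Among the 8 splits that part all 4 pairs of hemispheres, the highest other gave 0 genes by edgeR.

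In 12 of 231 groups of 4 libraries (5.19%), 1 library lay apart from the other 3 by Dixon's test, which chance gives in about 1 in 20. In CCI contralateral libraries these were Aif1 at 8.73 CPM in animal 3 (others 6.43 to 6.77), Cxcl10 at 0 CPM in animal 3 (others 0.712 to 0.838) and Bst2 at 2.8 CPM in animal 1 (others 4.05 to 4.3). By list mean on the log2 CPM scale they were MHC class I at 2.92 in animal 1 (others 3.4 to 3.43), olfactory bulb at 3.89 in animal 2 (others 2.55 to 2.59) and skeletal muscle at 2.37 in animal 1 (others 2.62 to 2.66). In CCI ipsilateral libraries they were Cxcl10 at 2.82 CPM in animal 1 (others 6.17 to 6.3), Insig1 at 55 CPM in animal 1 (others 61.2 to 62.4) and P2ry12 at 32.7 CPM in animal 2 (others 45.6 to 48.4). By list mean they were homeostatic microglia at 5.28 in animal 2 (others 5.66 to 5.71), red blood cells at 3.18 in animal 3 (others 3.75 to 3.86) and midbrain and hindbrain at 2.69 in animal 5 (others 2.1 to 2.16).

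The hemisphere effect differed between CCI and sham animals for 1165 genes by edgeR. Among named genes, the log2 difference of the effects was 5.36 for Lgals3, 4.525 for Lyz2, 4.41 for Hmox1, 4.37 for Spp1, 4.21 for Gpnmb and 3.08 for C3. The fitted value of 3.53 for Ccr2 rests on 2 counts in the sham ipsilateral libraries and became 2.69 without sham ipsilateral 4 (edgeR adjusted p = 0.0929) and 6.84 without sham ipsilateral 6, where 0 counts remain. The difference was 2.35 for Cd68, 2.33 for Tnc, 2.21 for Isg15, 2.06 for Serpina3n, 1.88 for Cd74, 1.497 for Gfap, 1.45 for C1qa, 1.42 for Aif1, 0.89 for Ctsb and 0.73 for Apoe. The fitted value of 8.62 for Arg1 is set by 0 counts in the sham ipsilateral libraries and is no bound. Negative differences were -1.59 for Egr2, -1.295 for Arc, -1.27 for Nr4a1, -1.20 for Abhd12b, -1.13 for Egr1, -0.77 for Lamp5 and -0.48 for Snap25.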

How the results depend on the processing

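The fits with the 6 paired animals together and without CCI contralateral 1 and 5 were added after the data were seen; the cause of the changes below was not tested. The count of genes called contralaterally was 37 with DESeq2, 1 with limma voom, 106 without a filter, 41 with only the groups compared, 9 without CCI contralateral 1 and 5, and 1 to 34 when 1 library was left out. Between sham hemispheres it was 4 with DESeq2, 26 without a filter, 23 with only the groups compared, 0 with log2(TPM + 1) (991 at an unadjusted p under 0.05), 3 with log2(TPM + 0.1), 303 with the animal as a block, 5 with the block over 6 animals and 0 to 8 when 1 library was left out. Leaving out 1 library gave 1695 to 3477 genes for CCI ipsilateral against sham ipsilateral and 392 to 1469 for the difference of effects, the lowest of both without sham ipsilateral 6; the latter was 721 with log2(TPM + 0.1). With an estimated correlation camera called 11, 0, 12, 0 and 9 lists in the ipsilateral, contralateral, CCI hemisphere, sham hemisphere and difference comparisons; fry called 0 contralaterally and 0 between sham hemispheres. With the preset correlation camera called 8 lists between sham hemispheres, and 5 (without sham ipsilateral 6) to 12 (without sham contralateral 6) when 1 library was left out. Between sham hemispheres, genes near no change turned sign, at adjusted p of 0.773 or more: with the block and the block over 6 animals Gfap was at 0.052 and 0.050, Cx3cr1 0.11 and 0.11, Tmem119 0.17 and 0.17, P2ry12 0.14 and 0.14, Itgam 0.14 and 0.14, Aif1 0.0074 and 0.0091, and Spp1 0.0036 and 0.0026. Tmem119 was at 0.015 with voom, 0.0155 with log2(TPM + 1) and 0.0166 with log2(TPM + 0.1), P2ry12 at 0.0026 with voom, C1qa at -0.00026 with upper-quartile scaling, and Trem2 at -0.0875 and -0.091 with TPM. Leaving out 1 library there gave log2 ranges of -0.57 to 0.0057 for Aif1, -0.20 to 0.048 for Gfap, -0.095 to 0.70 for Cd74, -0.29 to 0.097 for Cd68, -0.26 to 0.14 for Itgam, -0.32 to 0.42 for Gpnmb, -0.17 to 0.19 for Ifit3, -0.24 to 0.20 for Tmem119, -0.087 to 0.099 for C1qa, -0.35 to 0.115 for Cx3cr1, -0.14 to 0.0030 for Spp1, -0.15 to 0.20 for Trem2 and -0.22 to 0.14 for P2ry12. Contralaterally they were -0.20 to 0.23 for Isg15, -0.016 to 0.12 for Apoe, -0.21 to 1.56 for Arg1 and -0.0049 to 0.067 for Ifnar1. Apart from the changes given beside the results, the block changed no other call of a named gene or list described. Where leaving out a library left 1 in sham ipsilateral, that library was assumed to vary like the other groups. Genes with few counts, such as Ccl2 and Cxcl10 in contralateral libraries, are limited by depth.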

Other observations

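The ribosomal protein genes were looked at after their values were seen. Of 78 such genes, 60 were higher and 0 lower by edgeR in CCI than in sham ipsilateral libraries, with a median log2 fold change of 0.296. The medians of 10000 matched random lists ran from -0.124 to 0.0493. Their members were drawn independently, so this bears on length, GC content and expression only. Contralaterally the median of the 78 genes was 0.0903, and between the hemispheres of CCI animals 0.0216, with 3 genes higher and 3 lower. Between sham hemispheres the median was -0.2, with 73 of the 78 genes negative and 1 passing the test. The mean log2 CPM of these genes was 6.745 and 6.656 in the 2 sham ipsilateral libraries and 6.827 to 7.067 in the other 11.

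The growth hormone gene Gh, a pituitary gene chosen after its values were seen, was at 69.1 CPM in the CCI contralateral library of animal 5 and at 0, 0 and 0.806 CPM in those of animals 1, 2 and 3. Gh was at 5.11 CPM in the CCI ipsilateral library of animal 5 and at 0.134, 0 and 0 CPM in those of animals 1, 2 and 3. In sham libraries Gh was at 19.7, 10.5 and 8.47 CPM contralaterally (animals 4, 6 and 8) and at 2.41 and 16 CPM ipsilaterally (animals 4 and 6).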
